A study of Bos indicus with 48 samples.

How the data were processed

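RNA from needle biopsies of the longissimus dorsi of 48 Bos indicus cattle was extracted with TRIZOL and purified on RNeasy columns, then amplified, labelled with Cy3 and hybridized to single-colour Agilent arrays, one per animal, per the labels' protocols. Images were read with Agilent Feature Extraction 9.1, per the submitters' processing notes. The deposited table gives one value per probe and array, called a score here because the authors state neither its unit nor the steps after image reading. It holds 19265 probes for 48 arrays with 0 missing values and 0 pairs of identical arrays. The values, from -0.80 to 23.02, have the distribution of a log scale. The direction is known, since a larger value of a single-colour array means a brighter spot, while the base and scale of the logarithm and the centring stay unknown. The design written in advance assumed a log2 scale, and the same test was applied to the values as they are. Differences are therefore in units of the deposited log-scale values.

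The medians of the arrays, in the order of the replicate numbers, were as follows. In NSW animals of genotype 000 they were 8.66, 8.65, 8.67, 8.66 and 8.67 with implant and 8.65, 8.64, 8.66, 8.67, 8.66, 8.63 and 8.64 without. In NSW animals of genotype 220 they were 8.77, 8.80, 8.76 and 8.80 with implant and 8.72, 8.71, 8.71 and 8.72 without. In NSW animals of genotype 221 they were 8.77, 8.78 and 8.80 with implant and 8.66, 8.62 and 8.64 without. In WA animals of genotype 000 they were 8.62, 8.61, 8.59 and 8.62 with implant and 8.69 and 8.69 without. In WA animals of genotype 220 they were 8.50, 8.52, 8.50 and 8.53 with implant and 8.50, 8.51, 8.50 and 8.49 without. In WA animals of genotype 221 they were 8.81, 8.81, 8.83 and 8.82 with implant and 8.74, 8.75, 8.76 and 8.74 without. The number of arrays limits the precision. Signal over background is unknown, since no detection call or background value was used here.

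Groups were taken from the titles and characteristics of the labels, which agree for all 48 animals. Other label fields give another genotype for 8 WA animals. The source names of the 4 implanted animals of genotype 000 read 220, and the descriptions of the 4 animals of genotype 220 without implant read 000. Each reading was tried as an alternative. Replicate numbers are not stated to pair animals, and deviations from group means correlated at a mean of 0.016 between animals of the same number in different groups and of -0.0043 between animals of different numbers.

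Because array medians differed between groups, each array was centred on its 75th percentile, and the dimmest 20% of probes were left out, which left 15412. limma 3.58.1 in R 4.3.3 fitted 12 group means with 36 residual degrees of freedom. Contrasts averaged groups equally and gave the implant effect overall and in each site, the site effect, the 3 genotype comparisons and the interactions. P-values are two-sided, adjusted by the Benjamini-Hochberg method over all probes tested in each comparison, with a threshold of 0.05. Groups, comparisons, this model, the filter and the rule for naming probes were chosen before the data were examined. Figures were drawn with Python 3.11.15.

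A second fit was added after the data were examined, because animals of a group proved far more alike than animals of different groups. It applied limma to the 12 group means in an additive model of site, genotype and implant with 7 residual degrees of freedom, adding the interaction concerned where one was tested. Variance between group means was divided over the terms of the design, and its shares were compared with all 32 arrangements of implant or site, and all 216 arrangements of genotype, over whole groups within levels of the other factors.

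Both fits were tested on simulated data for the implant comparison over 15412 probes, with 50 probes changed at each of 4 sizes. With spread between animals alone, animals as units recovered 2%, 44%, 92% and 98% of shifts of 0.05, 0.1, 0.2 and 0.4 units with 8 false calls among 15212 unchanged probes, and group means recovered 0%, 32%, 78% and 96% with 2 false calls. With random differences between groups added, of the size of the observed site by genotype by implant term, animals as units made 7515 false calls and group means 11. These differences were drawn once and independently for each probe.

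In each comparison the probes named were those past the threshold with animals as units and with the same sign in both sites, or in both implant states for the site comparison, at most 2 per direction by size of difference. For the interactions they were the probes with the smallest p. A_73_121356 is named for the site by genotype test after its values were seen. The deposited table does not pair probe identifiers with gene names, and 0 of the identifiers were found in the gene table used, so the 45 gene lists written in advance, the calpain and calpastatin genes, both set tests and averages over the probes of a gene were not run.

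Alternatives planned in advance were quantile normalization, centring on the median, no filter on dim probes, leaving out the dimmest 50%, an intensity trend with robust variances, array weights, a replicate block, an additive model, the other readings of the labels, fits of each site alone and leaving out each animal in turn. Added after the data were examined were the values as deposited, the group means as units under each scaling, group as a random block, group means without the 2 groups whose labels disagree, and each group left out in turn.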

Results

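Gene expression was measured in needle biopsies of the longissimus dorsi, the long muscle of the back, from 48 Bos indicus cattle at 2 sites in Australia, New South Wales (NSW, 26 animals) and Western Australia (WA, 22 animals). The animals belonged to 3 tenderness genotypes. The 3 digits of a genotype score the alleles of calpastatin, calpain 3 and calpain 1 in that order, where 2 is the favoured (tender), 1 the intermediate and 0 the unfavoured (tough) genotype, so the genotypes compared were 000, 220 and 221. Calpains are calcium-dependent proteases of muscle, and calpastatin is their inhibitor. Within each site and genotype some animals had received a Revalor-H implant (200 mg of the androgen trenbolone acetate and 20 mg of estradiol) 2 months before biopsy and the others had not. The 12 groups held 2 to 7 animals. In NSW there were 5 implanted and 7 other animals of genotype 000, 4 and 4 of 220, and 3 and 3 of 221. In WA there were 4 implanted and 2 other animals of genotype 000, and 4 and 4 of both 220 and 221. One single-colour array was made per animal, with 19265 probes. The number of arrays limits the precision, and no detection call or background value was used here.

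Values are on a log scale whose base and scale were not stated, so differences are given in log-scale units and not as folds. The deposited values ran from -0.80 to 23.02. A mean ± SD over several groups is the average of the group means, with the SD and n of all their animals pooled. Probes are named by their array identifiers because none of the identifiers was paired with a gene in the sources used here. The calpain genes and the preset gene lists were therefore not measured by name. The counts of the comparisons are given with the 48 animals and with the 12 group means as units of replication, except that of the site by genotype by implant interaction, which is given with animals only.

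Animals of a group resembled each other far more than they resembled animals of any other group. All 48 arrays had their nearest array within their own group. The root mean square difference between 2 arrays over the 15412 probes tested was 0.129 to 0.1997 units within groups and 0.273 to 0.581 units between groups. The median probe had an SD of 0.087 between animals of a group and of 0.205 between the 12 group means. The mean of all deposited values of an array was nearly constant within each group, with a highest SD of 3.0e-04, while the group averages of that mean ran from 8.95 to 9.20. Taking animals as units, limma called a site by genotype by implant interaction in 12370 of the 15412 probes at an adjusted p under 0.05. Measured against the deposited spread between animals, group means thus differed in most probes in ways that none of the 3 factors alone describes. In simulated data holding random group differences of that size and no implant effect in 15212 unchanged probes, the fit with animals as units made 7515 false calls for the implant comparison and the fit with group means as units made 11. The fit to group means recovered 38% of implant shifts of 0.4 units, 86% of shifts of 0.8 units and 100% of shifts of 1.6 units, each over 50 probes. The adjusted threshold loosens as more changed probes are recovered, so these 11 false calls are not the number to expect in the real comparison. No data without changed probes were simulated. The group differences were drawn once and independently for each probe. Deviations of a group shared between probes, which could make false calls come together, were therefore not simulated. P-values with animals as units take the deposited spread between animals as it is. Counts from both fits are given, and verbs of change are kept for the calls of the group-mean fit, which was added after the data were examined.

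**Figure D1:**
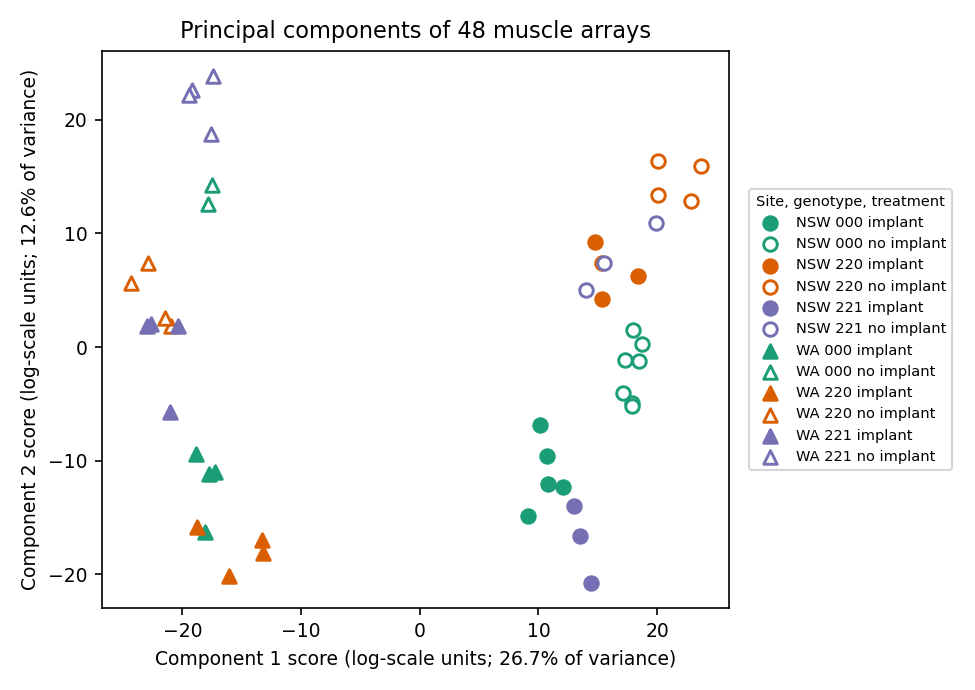
Scores of the 48 arrays on the first and second principal components of the 15412 probes tested, in log-scale units after centring each array on its 75th percentile; each point is an animal, shape gives the site, colour the genotype and filling the implant. WA animals lie between -24.3 and -13.2 on component 1 and NSW animals between 9.13 and 23.7, and implanted animals have a lower mean on component 2 in all 6 site and genotype combinations.

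The first comparison asked what the implant did to muscle expression. Implanted muscle had raised levels of 11 probes and lowered levels of none when the 12 group means were the units (limma, adjusted p under 0.05). All 11 were higher in implanted animals in 6 of 6 site and genotype combinations, by 0.45 to 6.13 units in single combinations. The fit that picked them rests on these same differences, so their shared direction is not separate support. Averaged over the combinations the differences were 0.66 to 4.39 units, and 5 of them exceeded 1 unit. Group means under quantile normalization and under median centring gave 12 raised probes each, and the values as deposited gave 22, with none lowered in any of these (limma; 1419, 1365 and 1378 at an unadjusted p under 0.05). Lowered probes were called with group as a random block (70 raised, 8 lowered) and without the 2 groups with disagreeing labels (7 raised, 1 lowered). Leaving out 1 group gave 9 to 17 probes, and several of these fits also called lowered probes. Without the implanted NSW 220 group 15 of 17 were raised, and without the implanted NSW 000 group 13 of 15. Without the implanted WA 221 group 11 of 15 were raised, and without the implanted WA 000 or WA 220 group 10 of 11. Without the NSW 221 group that had no implant 11 of 12 were raised. In the remaining fits all were raised. The strongest rise was in A_73_109689, which stood at 9.98 ± 0.18 (SD, n = 24) without the implant and at 14.37 ± 1.07 (SD, n = 24) with it, a rise of 4.39 ± 0.32 units (SE; adjusted p = 0.00015 in limma on group means). The lowest implanted animal, at 12.64, lay above the highest animal without implant, at 10.27. A_73_111233 rose from 6.63 ± 0.14 to 8.75 ± 0.55 (SD, n = 24 each), by 2.12 ± 0.16 units (SE; limma adjusted p = 0.00015), again with no overlap between implanted animals (7.94 to 9.64) and the others (6.36 to 6.86).

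The probes with the largest lower values in implanted animals were less even. A_73_103255 was 10.35 ± 1.01 in implanted animals against 12.06 ± 0.82 in the others (SD, n = 24 each), a difference of -1.72 ± 0.16 units with animals as units (limma adjusted p = 5.1e-12). It was lower in 6 of 6 combinations, with differences of -3.06 to -0.84 units, but the group-mean fit gave an SE of 0.44 and an adjusted p of 0.22 (limma). A_73_107411 was 5.96 ± 1.81 against 8.06 ± 2.53 (SD, n = 24 each), with a difference of -2.10 ± 0.22 units (limma adjusted p = 1.9e-10 with animals, 0.58 with group means), and it was higher in implanted 220 animals of NSW by 2.00 units.

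With animals as units, 10342 probes passed the threshold for the implant (limma), 6113 higher and 4229 lower. This split depended on the scaling, since centring each array on its median gave 4875 higher and 5231 lower. The implant accounted for 10.96% of the variance between group means, the highest of the 32 ways of exchanging whole groups between implanted and not implanted within site and genotype (one-sided exact permutation test, p = 0.031, the smallest p these arrangements can give, next highest 9.90%). If each degree of freedom took the same, its share would be 9.09%. On component 2, which held 12.6% of the variance between arrays, implanted groups scored lower in 6 of 6 combinations, with differences of -25.4 to -7.85. Across probes, implant differences in one combination correlated with those in another at a mean r of 0.108 (-0.06 to 0.35 over 15 pairs), where probes are not independent replicates. A single direction in all 6 combinations was seen in 1037 probes (738 higher, 299 lower), or 6.73%, against 3.13% by chance.

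**Figure D2:**
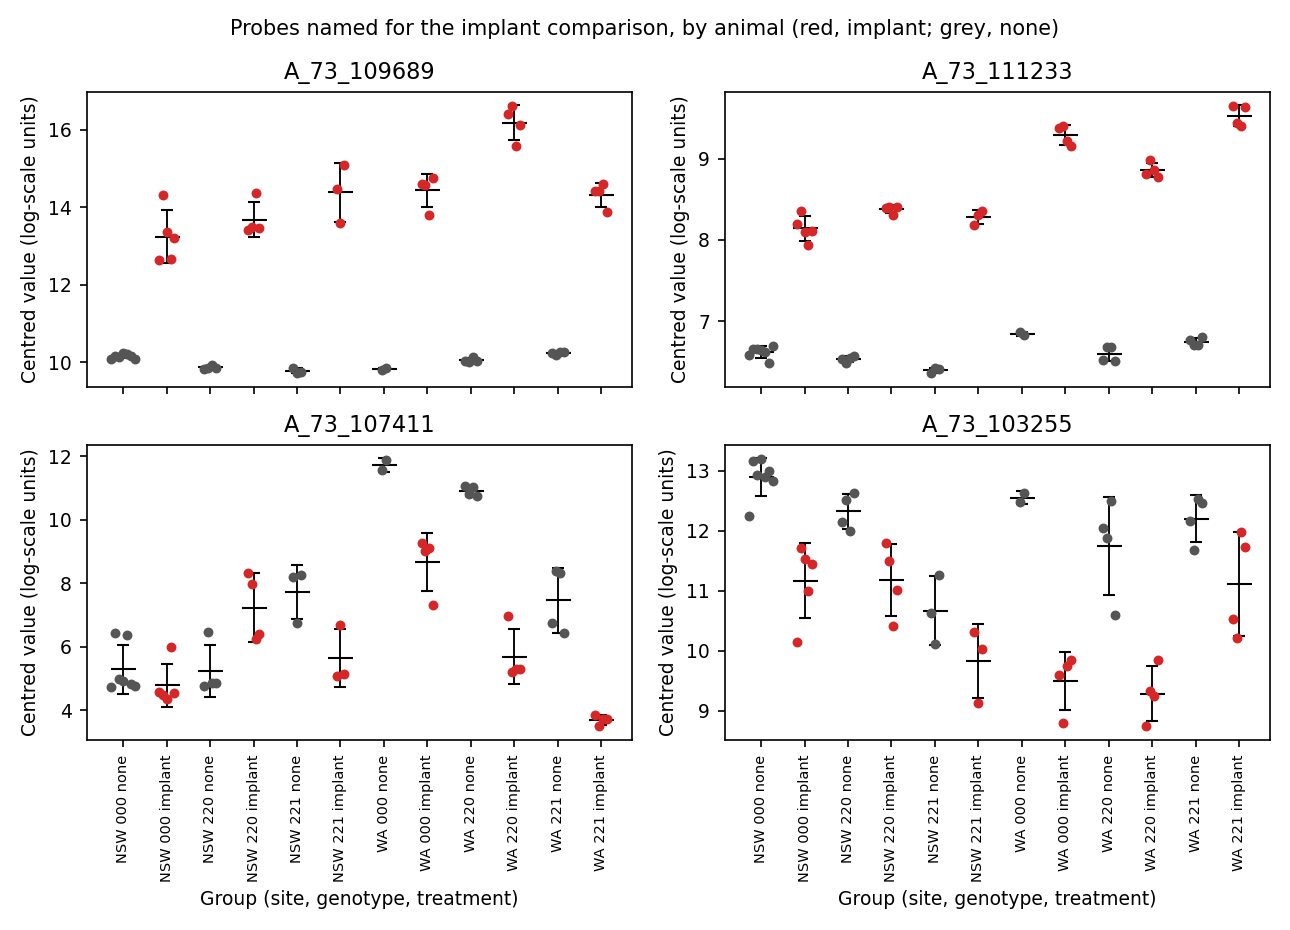
Centred values (log-scale units) of the 4 probes named for the implant comparison, by group (site, genotype, treatment); each point is an animal, red with and grey without implant, and black bars give the group mean ± SD. A_73_109689 and A_73_111233 are higher in every implanted animal, A_73_103255 has a lower mean in implanted animals of all 6 site and genotype combinations, and A_73_107411 goes the other way in 220 animals of NSW.

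Within sites, the implant raised 9 probes and lowered 3 in WA, and raised 4 and lowered none in NSW, with group means as units (limma). All 4 NSW probes were among the 12 WA probes and among the 11 probes of both sites together. A_73_109689 differed by 4.94 units in WA and 3.83 in NSW, and A_73_111233 by 2.49 and 1.75. With animals as units these site differences of -1.11 ± 0.22 and -0.74 ± 0.05 units (NSW minus WA, SE) passed the threshold (limma adjusted p = 3.2e-05 and 4.6e-14), whereas with group means their adjusted p were 0.86 and 0.77 (limma). Across all probes the implant difference in WA correlated with that in NSW at r = 0.168. At the level of animals, 9996 probes passed in WA (5268 higher) and 9889 in NSW (6272 higher, 3617 lower; after quantile normalization 4690 higher and 4767 lower, and after median centring 4130 and 5440). Of the 6423 probes that passed in both sites, against 6414 expected of independent lists, 3760 had the same direction.

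The test of the difference between sites in the implant effect found 0 probes with group means as units, 913 at an unadjusted p under 0.05 where 771 would be expected, and 9267 with animals as units (limma throughout). The animal-level probes with the smallest p were A_73_103016 and A_73_113140, with a more positive implant difference in NSW by 1.01 ± 0.06 and 0.67 ± 0.04 units (SE), and A_73_111865 and A_73_110762, with a more positive one in WA, by -1.02 ± 0.06 and -0.83 ± 0.05 units (NSW minus WA). In A_73_103016 the implanted WA groups stood at 5.90 to 6.12 and the other WA groups at 6.65 to 6.89, while the NSW groups lay between 5.84 and 6.49. The group-mean adjusted p of these 4 probes were 0.67 to 0.70 (limma). The split of the animal-level calls, 5266 positive and 4001 negative, became 4313 and 5049 under quantile normalization and 3818 and 5794 under median centring.

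Between sites, muscle of NSW and WA animals differed in many probes. Each site was a single location, so its group means are not independent replicates of a site. Whatever else differed between both locations, such as handling or batch, cannot be told apart from site here. With group means as units 2055 probes passed the threshold (limma), 1137 higher and 918 lower in NSW, and 1733 of them had a single direction in all 6 genotype and implant combinations. The fit that picked them favours such probes. The values as deposited gave 1121 higher and 454 lower, and leaving out the 2 groups with disagreeing labels gave 905 probes (482 higher, 423 lower). Group as a random block gave 3095 (1740 higher, 1355 lower; limma). Leaving out 1 group gave 1211 to 1946, with the lowest counts without the NSW 220 (1211), WA 220 (1259) and NSW 000 (1351) groups that had no implant and the implanted WA 221 group (1339). The median size of these differences was 0.457 units, and 124 exceeded 1 unit, 49 higher and 75 lower in NSW. A_73_101038 was higher in NSW, at 16.11 ± 0.46 (SD, n = 26) against 13.38 ± 1.10 (SD, n = 22), by 2.73 ± 0.40 units (SE; limma adjusted p = 0.0026 on group means). A_73_111154 was higher in NSW by 2.21 ± 0.35 units (limma adjusted p = 0.0037). A_73_119171 was lower in NSW, at 9.85 ± 0.99 (n = 26) against 12.96 ± 1.19 (n = 22), by -3.12 ± 0.51 units (limma adjusted p = 0.0041).

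A_73_112168 was also lower in NSW, by -2.80 ± 0.81 units (limma adjusted p = 0.042 on group means), in 5 of 6 combinations; in implanted 220 animals it was higher in NSW by 1.15 units. Its call was lost on group means in the values as deposited (limma adjusted p = 0.052) and without the 2 groups with disagreeing labels (0.14), within a range of 0.021 to 0.14 over the fits with groups as the unit. The other named site probes kept their direction in 6 of 6 combinations, but A_73_101038 differed by only 0.43 units and A_73_111154 by 0.51 units between 000 animals without implant, where WA had 2 animals. Taking animals as units, 11994 probes passed (6239 higher and 5755 lower in NSW; 7835 and 4306 in the values as deposited). Site took 28.3% of the variance between group means, the largest share of the 32 arrangements of whole groups (one-sided exact permutation test, p = 0.031, the smallest these arrangements can give, next highest 18.6%). Site differences correlated between combinations at a mean r of 0.335 (0.16 to 0.52 over 15 pairs) across probes, and 2780 probes, 18.0%, had a single direction in all 6, against 3.13% by chance.

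**Figure D3:**
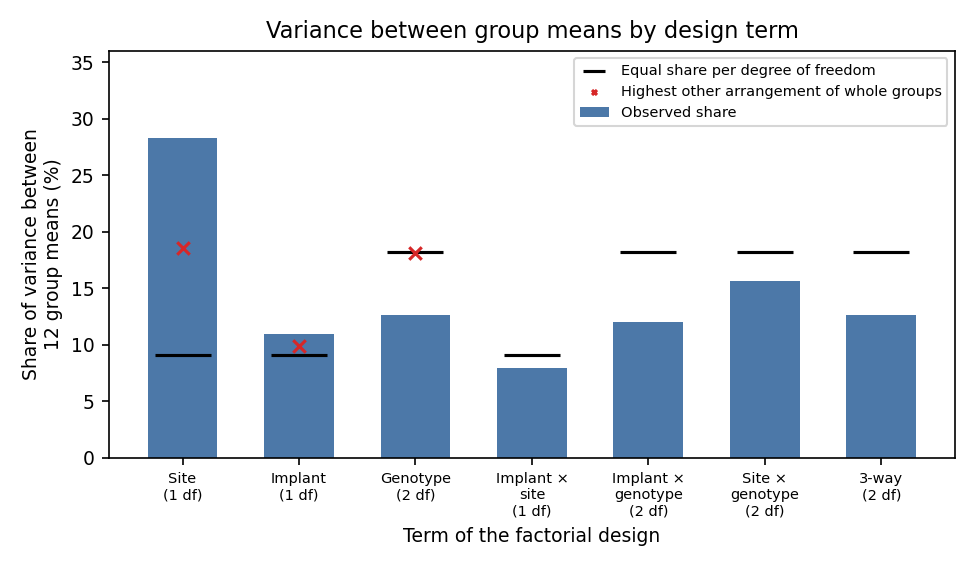
Share (%) of the variance between the 12 group means taken by each term of the design over the 15412 probes tested; bars give the observed share, black marks the share if each degree of freedom took the same, and red crosses the highest share among the other arrangements of whole groups. Site (28.3%) and implant (10.96%) lie above both marks and genotype (12.6%) lies below both. The black marks are at 9.09% for site and for implant and at 18.2% for genotype.

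The tenderness genotypes were compared to find expression differences that go with the favoured alleles. No probe passed for 220 against 000, for 221 against 000 or for 221 against 220 with group means as units (0 in each, limma; 575, 600 and 450 probes at an unadjusted p under 0.05, where 771 would be expected; 0 in each with group as a random block). This fit counts genotype differences that vary with site or implant as error, which can also lower the unadjusted counts. How well it recovers genotype differences was not simulated. At the level of animals, 9214, 8264 and 8220 probes passed. Genotype took 12.6% of the variance between group means, and 133 of the 216 arrangements of genotype over whole groups within site and implant state gave as much (one-sided exact permutation test, p = 0.616). If each degree of freedom took the same, its share would be 18.2%. Genotype differences correlated between the 4 site and implant combinations at mean r of 0.01, -0.01 and -0.03 across probes for the 3 comparisons.

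For 220 against 000, A_73_107238 was lower in 220 animals in 4 of 4 combinations, at 11.76 ± 0.75 (SD, n = 16) against 12.75 ± 0.34 (SD, n = 18), a difference of -0.996 ± 0.147 units with animals as units (limma adjusted p = 4.2e-07; 0.99 with group means). A_73_121356 was lower in 4 of 4, by -0.98 ± 0.19 units (limma adjusted p = 3.0e-05; 0.99 with group means). Higher in 220 were A_73_115812, by 2.54 ± 0.17 units, and A_73_119440, by 1.74 ± 0.30 units and in 3 of 4 combinations (limma adjusted p = 1.6e-14 and 5.0e-06; 0.99 for both with group means). The difference in A_73_115812 was 4.75 units in WA and 0.32 in NSW, and the 2 WA animals of genotype 000 without implant averaged 11.09 ± 0.73 where the other 11 groups averaged 18.19 to 20.95. The animal-level calls split into 4071 higher and 5143 lower, or 5093 and 4133 after median centring. Other readings of the labels were tried in an additive model, in which both A_73_115812 (1.49 units) and A_73_121356 (-1.23 units) passed with the genotypes used here. In that model, genotypes from the descriptions ended the animal-level calls of A_73_115812 (1.28 units) and A_73_121356 (-0.77 units), genotypes from the source names ended neither, and leaving out the 8 animals with disagreeing labels ended that of A_73_115812 (1.73 units).

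For 221 against 000, A_73_120661 was lower in 221 animals in 4 of 4 combinations, at 7.55 ± 0.75 (SD, n = 14) against 9.25 ± 0.62 (SD, n = 18), by -1.70 units (SE 0.16 with animals and 0.30 with group means; limma adjusted p = 3.2e-11 and 0.75). It was the only probe that passed in this comparison when the 2 groups with disagreeing labels were left out of the group-mean fit (limma). A_73_108569 was lower by -1.90 ± 0.31 units in 3 of 4 combinations, and A_73_111871 was higher by 1.96 ± 0.23 units in 3 of 4 (limma adjusted p = 2.2e-06 and 5.9e-09 with animals, 1 for both with group means). A_73_115812 was higher by 3.36 ± 0.18 units, again mostly in WA (5.98 units, against 0.74 in NSW), where the SE is that of animals (limma adjusted p = 4.3e-17); with group means the SE was 1.36 and the adjusted p 1 (limma). In the additive model the difference in A_73_115812 was 2.44 units with the genotypes used here. There it was 2.80 units with genotypes from the source names, 2.15 from the descriptions and 2.75 without the 8 animals with disagreeing labels, and it passed in each. The animal-level split of 3790 higher and 4474 lower became 9116 and 1251 in the values as deposited, in which the median of all probes was 0.10 units higher in 221 than in 000.

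The comparison of 221 with 220 covers a single step of the calpain 1 score at equal calpastatin and calpain 3 scores. A_73_119440 and A_73_110405 were lower in 221 in 4 of 4 combinations, by -2.33 ± 0.30 and -2.01 ± 0.16 units (SE, animals as units; limma adjusted p = 5.9e-08 and 7.7e-13, 1 for both with group means). A_73_110405 stood at 11.09 ± 1.47 (SD, n = 14) in 221 and 13.10 ± 0.95 (SD, n = 16) in 220. A_73_111871 and A_73_108788 were higher by 1.87 ± 0.23 and 1.62 ± 0.39 units, each in 3 of 4 combinations (limma adjusted p = 1.6e-08 and 0.00061, 1 for both with group means). The call of A_73_108788 ended in the additive model with the genotypes used here (1.501 units). In the same model its difference was 1.10 units with genotypes from the source names, 0.92 from the descriptions and 0.90 without the 8 animals with disagreeing labels. The animal-level split of 4343 higher and 3877 lower became 10294 and 1033 in the values as deposited, in which the median of all probes was 0.10 units higher in 221 than in 220.

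One probe passed the site by genotype test with group means as units, A_73_121356 (limma adjusted p = 0.00099; 2.3e-12 with animals). In NSW it fell from 9.104 and 8.78 in 000 animals (with and without implant) through 8.30 and 7.30 in 220 to 6.57 and 6.19 in 221. In WA it ran from 7.72 and 7.01 in 000 through 6.86 and 6.24 in 220 to 9.45 and 8.55 in 221, so that 221 animals had the lowest level in NSW and the highest in WA. At the level of animals, 12729 probes passed this test, led by A_73_107642 and A_73_112259 (limma adjusted p = 6.0e-18 and 1.3e-17; 0.66 and 0.41 with group means). The test for an implant effect that differs between genotypes found 0 probes with group means (limma; 453 at an unadjusted p under 0.05) and 12331 with animals. In A_73_103267, which with A_73_108571 had the smallest p there (limma adjusted p = 1.1e-16 and 8.0e-17; 1 for both with group means), WA groups with and without implant stood at 8.41 and 7.75 in 000, 8.58 and 7.32 in 220, and 7.36 and 8.12 in 221. NSW groups stood at 7.79 and 7.998 in 000, 7.98 and 7.88 in 220, and 8.17 and 8.59 in 221, so in 000 the direction was opposite to that in WA.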

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

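Tests in this part were chosen before their results were seen, except the count after quantile normalization, the ratio with spread from different animals, the arrangements of genotype within site and the fits to group means.

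The 12 groups lay apart in most probes, with a site by genotype by implant interaction in 12370 of 15412 probes. After quantile normalization 98.8% as many passed. Each array had already been centred for the first count, so comparing both counts cannot test a level shift per group. Quantile normalization gives all arrays the same distribution of values. The comparison therefore argues only against differences in that distribution as the cause of most of these calls. Shifts of single probes per group left by the normalization were not tested. Deviations of animals from their group reduced by one factor before deposit stay open, and would make the SDs within groups and the p-values with animals as units given in the results too small. The median F of that interaction fell from 17.3 in the tenth of probes with the smallest spread within groups to 7.78 in that with the largest, which was 65.2% of that in probes of middle spread (95% bootstrap interval 58.9 to 73.6) and above the bound of 50% set beforehand. Since this sorts probes by the denominator of F, the spread for sorting and that in the ratio were also taken from different animals. That gave 68.4% (62.8 to 76.9) and, with both sets exchanged, 80.8% (73.8 to 91.4), below the equal ratios expected if one factor were the whole cause. These intervals come from resampling probes, which share the same animals and are not independent. They leave out the sampling of animals and groups. Each group handled as a batch of its own cannot be told apart from site, genotype and implant, whose biology is untested here, because 0 label fields give a slide, date or batch. The deposited values do bear marks of their group. Array means had an SD within groups of at most 3.0e-04, and array SDs one of at most 0.0025. Across all arrays the SDs ran from 3.84 to 3.94, and group averages of the mean from 8.95 to 9.20. Processing each group by itself before deposit would leave such values, and what it did to single probes was not tested.

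Counts with animals as units were compared with other arrangements. Among random regroupings of animals, 100 per comparison with the real one included, only 1, the real one, reached the real count in each. The real count and the highest other were 10342 and 4975 for the implant, 9996 and 4988 for the implant in WA, and 9889 and 6325 for the implant in NSW. They were 11994 and 3423 for site, 9214 and 662 for 220 against 000, 8264 and 349 for 221 against 000, and 8220 and 311 for 221 against 220. For the interactions they were 9267 and 6153 (implant by site), 12331 and 7109 (implant by genotype), 12729 and 5052 (site by genotype) and 12370 and 6200 (all 3 factors). Such regroupings mix animals that lie apart, which raises the error (the median of the other counts was 0 in each comparison), so they show that animals of a group lie together and exclude neither chance differences between whole groups nor deviations reduced before deposit.

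Moving whole groups tests that. For site, only 1 of 32 arrangements, the real one, reached the real count of 11994 (highest other 11534). That is the fewest this test can give, so it makes chance differences between whole groups less likely but does not exclude them. Nor can it tell site from anything else shared by all groups of a location. For the implant they are not excluded by the count, since 2 of 32 reached 10342 (highest other 10401), although the implant's share of the variance was the highest of the 32. For genotype they are not excluded, with 85 of 216 arrangements reaching 9214 for 220 against 000 (highest other 10595), 150 of 216 reaching 8264 for 221 against 000 (highest other 10621) and 165 of 216 reaching 8220 for 221 against 220 (highest other 10843). The median count of the other arrangements was 9267 for the implant and 10177 for site, which points to a structure of the groups.

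Genotype differences of implanted and not implanted animals of one site correlated across probes at a mean r of 0.215 for 220 against 000 and 0.114 for 221 against 220, but at -0.07 for 221 against 000, while between sites they correlated at -0.09, -0.10 and 0.01 in that order. Differences between whole groups that do not follow genotype within site stay open, since 7 of 36 arrangements gave as large a share for genotype within site (28.2%, highest other 30.8%). An effect of genotype that depends on site may exist as well and is untested beyond the interaction, which called 1 probe with group means as units (limma).

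Differences in effect between sites or implant states passed with animals as units in 10 of the probe comparisons named. The implant difference in NSW minus that in WA was -1.11 units for A_73_109689, -0.74 for A_73_111233, 3.82 for A_73_107411 and 0.97 for A_73_103255. The site difference with implant minus that without was 1.97 units for A_73_119171 and 1.05 for A_73_112168. The genotype difference in NSW minus that in WA was -4.43 units for A_73_115812 in 220 against 000 and -5.24 in 221 against 000, -0.88 for A_73_120661 in 221 against 000 and -2.77 for A_73_111871 in 221 against 220. Interactions passed in 9267 probes for implant by site, 12331 for implant by genotype and 12729 for site by genotype, against 0, 0 and 1 with group means as units (limma; 913, 453 and 1164 at an unadjusted p under 0.05).

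Single animals stood apart from the rest of their group in 34 of 234 sets of values tested, where chance, at about 1 in 20, gives 11.7. The rule compares the gap to the next value with the range of the set. A flagged gap can therefore be small in units, as for 10.14 against 10.03 in A_73_109689. The sets come from probes picked by their differences and from the same animals, so they are not independent and 11.7 is only a rough guide. None of 9 sets of array medians held one. Their causes were not tested.

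In implanted NSW animals of genotype 000, replicate 4 had 5.99 for A_73_107411 (next 4.57), replicate 1 had 14.78 for A_73_111154 (next 14.04) and 17.44 for A_73_111865 (next 17.60), replicate 2 had 6.16 for A_73_112168 (next 4.86), replicate 5 had 7.83 for A_73_119440 (next 6.40) and replicate 3 had 7.96 for A_73_120661 (next 8.88). In NSW 000 animals without implant, replicate 6 stood apart in 4 probes, with 12.25 for A_73_103255 (next 12.82), 16.54 for A_73_101038 (next 16.17), 5.53 for A_73_112168 (next 4.17) and 8.67 for A_73_120661 (next 9.36). Replicate 7 there had 19 for A_73_115812 (next 19.91), and replicate 1 had 5.74 for A_73_111871 (next 4.45).

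In implanted NSW animals of genotype 220, replicate 3 had 14.37 for A_73_109689 (next 13.48) and 8.31 for A_73_111233 (next 8.39), replicate 4 had 8.95 for A_73_119440 (next 10.87) and 11.57 for A_73_110405 (next 12.30), and replicate 2 had 7.84 for A_73_107642 (next 7.99). In NSW 220 animals without implant, replicate 2 had 6.47 for A_73_107411 (next 4.86) and 10.62 for A_73_108788 (next 13.66), and replicate 1 had 11.06 for A_73_110762 (next 11.31).

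In implanted WA animals of genotype 000, replicate 4 had 7.30 for A_73_107411 (next 9.02) and 10.51 for A_73_119171 (next 11.56), replicate 3 had 9.07 for A_73_119440 (next 10.64) and 18.08 for A_73_111865 (next 17.82), and replicate 1 had 6.01 for A_73_111871 (next 4.84). In implanted WA 220 animals replicate 1 had 6.97 for A_73_107411 (next 5.30). In WA 220 animals without implant, replicate 3 had 10.14 for A_73_109689 (next 10.03), replicate 4 had 12.44 for A_73_107238 (next 12.04), replicate 1 had 5.71 for A_73_111871 (next 4.73) and replicate 2 had 11.22 for A_73_108788 (next 14.05).

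In implanted WA animals of genotype 221, replicate 3 had 13.60 for A_73_101038 (next 12.78) and 17.74 for A_73_111865 (next 18.00). In WA 221 animals without implant, replicate 1 had 9.39 for A_73_108569 (next 7.47) and replicate 3 had 12.27 for A_73_110405 (next 13.22).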

How the results depend on the processing

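Tests chosen after the results were seen are the values as deposited, all fits to group means, group as a random block and the groups left out; the others were planned.

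With animals as units, all 11 counts stayed within 1.5 times their reported value under quantile normalization, median centring, the values as deposited, no filter, trend with robust variances, array weights and leaving out each animal in turn. The same holds for both single-site fits (9556 in WA, 10124 in NSW). The variance shares of site, implant and genotype stayed on the same side of the threshold of 0.05 in the exact permutation test under every setting in which they were computed, and none of the 24 probe comparisons with a signed difference reversed in the settings in which each was computed. The implant by site probes were not computed in the additive settings, with group as a random block or without the 2 groups whose labels disagree, nor probes below the filter with the dimmest 50% left out, nor those named for the other interactions in any setting. Where leaving out an animal left 1 in the WA 000 group without implant, the lone animal was assumed to vary like the others.

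With the replicate block the counts were 10172 for the implant, 11868 for site, 8996, 7976 and 8086 for 220 against 000, 221 against 000 and 221 against 220, 9860 and 9680 for the implant in WA and NSW, 9062 for implant by site, 12249 for implant by genotype, 12535 for site by genotype and 12288 for all 3 factors.

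Leaving out 1 animal gave 9852 to 10350 probes for the implant, 11630 to 11992 for site, 8302 to 9282 for 220 against 000, 7567 to 8411 for 221 against 000, 7831 to 8279 for 221 against 220, 9138 to 10074 and 9407 to 9946 for the implant in WA and NSW, 8773 to 9294 for implant by site, 11881 to 12336 for implant by genotype, 12286 to 12744 for site by genotype and 11916 to 12405 for all 3. Shares ran from 27.96 to 28.47% for site, 10.67 to 11.10% for the implant and 12.46 to 12.85% for genotype.

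With the dimmest 50% left out, fewer probes were tested, and the counts were 6281 (implant), 7719 (site), 5910 (220 against 000), 5293 (221 against 000), 5096 (221 against 220), 6198 and 6125 (implant in WA and NSW), 5841 (implant by site), 7748 (implant by genotype), 7885 (site by genotype) and 7757 (all 3).

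The additive model, which counts interactions as noise, gave 5158 probes for the implant and 4136, 3714 and 2834 for 220 against 000, 221 against 000 and 221 against 220. With genotypes from the source names these were 5640, 4459, 3985 and 2948, and from the descriptions 5897, 4794, 3720 and 3134. Without the 8 animals they were 5803, 5231, 3813 and 3254, with 7980 for site. Of the named probes, A_73_108788 lost its call in the additive model already (1.501 units), and there the other readings lowered its difference to 1.10 (source names), 0.92 (descriptions) and 0.90 units (without the 8 animals). With group means it was 1.62 units, and 0.93 without the 2 groups whose labels disagree. A_73_115812 (220 against 000) kept it there and lost it from the descriptions and without the 8 animals, and A_73_121356 kept it there and lost it from the descriptions.

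With the 12 group means as units (limma) the counts were 11 (implant), 2055 (site), 12 and 4 (implant in WA and NSW) and 1 (site by genotype), and 0 for the 3 genotype comparisons, implant by site and implant by genotype, where 575, 600, 450, 913 and 453 probes had an unadjusted p under 0.05. With quantile normalization as well they were 12, 2179, 13, 4 and 1, and 0 for those 5 comparisons (603, 632, 488, 925 and 442 unadjusted). With the values as deposited they were 22, 1575, 10, 4 and 1, and 0 for the same 5 (431, 937, 1001, 638 and 331). With median centring they were 12, 2019, 11, 4 and 1, and 0 for the same 5 (581, 603, 484, 896 and 445). For site, the values as deposited split into 1121 higher and 454 lower in NSW. The cause of the lower counts was not tested, since the error, the degrees of freedom and the model changed together (median SE 0.103 against 0.026 units for the implant). Of 24 probe comparisons, 18 lost their call with group means and 19 with the values as deposited, where A_73_112168 (site) was the added loss.

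Without the 2 groups whose labels disagree, group means gave 8 probes for the implant (7 higher, 1 lower), 905 for site, without the call of A_73_112168, 0 for 220 against 000 (769 unadjusted), 1 for 221 against 000 and 0 for 221 against 220 (484 unadjusted; limma). Leaving out each group in turn gave 9 to 17 probes for the implant, 1211 to 1946 for site, 0 for 220 against 000 and 221 against 000 in every fit, and 0 to 1 for 221 against 220, with the 1 found without the implanted NSW 000 group. Group as a random block (limma, correlation 0.798) gave 78 probes for the implant (70 higher, 8 lower), 3095 for site and 0 for each genotype comparison (715, 708 and 462 unadjusted).

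Averages over the probes of a gene and the set tests were not run, as no gene names were found. Signal over background is unknown, so its limit on dim probes could not be measured.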

Other observations

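The test in this part was chosen before its result was seen, on probes picked by the fit to group means, which was chosen after the data were examined.

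The 11 probes raised by the implant varied between implanted animals of one group, most of all A_73_109689, whose SD within groups was 0.530 units with implant and 0.054 units without. In 7 of the 11 the SD was larger in implanted animals, with a median ratio of 1.29 against 1.08 for all probes. In the others it was smaller, with ratios of 0.733 to 0.874. All probes also tended to a larger SD with implant, and their share was not computed. The count of 7 alone therefore does not set the 11 apart. A hypothesis is that implanted animals of one group differ in one shared strength of response, which would make these probes deviate together. Their deviations from group means correlated at a mean of 0.121 over 24 implanted animals (55 pairs of probes, -0.47 to 0.71) and at -0.03 over the 24 others, and 1.27% of 10000 random sets of probes with similar spread reached as high a mean (highest 0.247). Such a shared response may therefore be present, but the correlation is low, and other sources of shared deviation among implanted animals were not tested.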
